A study of Mus musculus with 4 samples.

How the data were processed

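Small RNA was sequenced from cauda epididymal sperm of 4 C57BL/6 mice, 2 per cross. Per the labels' protocols, sperm was washed in buffered saline, RNA of each mouse was extracted with Trizol and size-selected on a gel, libraries were made with the Illumina TruSeq small RNA kit, and the 4 barcoded libraries shared 1 lane. The submitters' processing notes name CASAVA 1.8.2, Bowtie 1.1.2 and the mouse build mm10, with no role or order. Read trimming, the feature annotations and the rule for reads that map to several places are not given in the sources used here.

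The deposited values are RPM, as the authors name the unit, in 2 tables, 1 per replicate number, each with 1 column per cross and 6 classes of feature named by the authors: tRNA, miRNA, piRNA, rRNA, repeats and RefSeq. Which reads the total behind RPM counts is not stated. A table lists 53800 or 66068 features, 49284 of them shared, and a feature listed in only 1 table was given 0 in the other. The commonest value of the miRNA class in a column was taken as the value of 1 read in the small RNA classes. It gave 1.58, 0.561, 0.642 and 0.238 RPM for the small RNA classes of original-cross replicates 1 and 2 and extra-cross replicates 1 and 2, so that the scale rests on 632859, 1782510, 1557770 and 4205690 reads. Many values sit at simple fractions of 1 read, as when a read with several matches is divided among features. Only 28.6% to 36.3% of values up to 20 reads were whole within 0.02 reads, so read counts were not recovered and no count model was run. The precision is lowest in original-cross replicate 1, where 10 RPM stands for few reads.

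For RefSeq, the value of 1 read was chosen among the commonest values as the one whose simple fractions were also common. In original-cross replicate 1 the commonest RefSeq value, 0.03015 RPM (seen 2512 times), was thereby read as a fraction of 0.0603 RPM (seen 2347 times). Taken as 1 read, it would give a larger ratio. With this choice the RefSeq rows of that library have a 1-read value of 0.0603 RPM, 26.2 times below that of the other classes. RefSeq was therefore left out of the first fit and analysed separately, with that column's RefSeq values multiplied by the ratio. Of 68434 RefSeq transcripts 55925 (81.7%) matched a gene symbol through the reference gene table, and their values were summed to 16785 genes. Transcript names and positions of ribosomal RNA came from the GENCODE mouse annotation of GRCm38, the assembly also called mm10. In the main analysis, values were log2(RPM + 1), features with a mean below 10 RPM over the 4 libraries were left out, and limma 3.58.1 in R 4.3.3 was fitted with cross type as the only term and a variance trend. Fold changes are on this scale and understate those of low features. Calls were made at a Benjamini-Hochberg adjusted p of 0.05 over 760 small RNA features and separately over 477 RefSeq genes. Lists with at least 3 tested members were tested with camera (preset correlation 0.01, and again with an estimated correlation) and with fry. Class shares were compared by an exact permutation test. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.

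The test was planned for counts, with limma as the stated choice for normalized values, and the latter was used. The lists, the settings and the naming rule were fixed before the data were examined, except the piRNA loci and the collagens as lists, the RefSeq rescaling, the voom weights, the fit with no variance trend and the fit with identical rows counted once. The text names the features past the threshold, or if fewer than 10 pass the 5 with the lowest p in each direction, the 10 most abundant features, and up to 4 of the most abundant measured members of each list. The rule was applied to the RefSeq genes as well, where its added lists were handled alike. Lists covered microRNA families and clusters, microRNAs and transcripts of epididymal epithelium, smooth muscle and stroma, and blood, tRNA by isoacceptor, small nucleolar, small nuclear, ribosomal, Y, vault, 7SK and 7SL RNA, repeat families, sperm transcripts, the piRNA pathway and DNA methylation genes. Mitochondrial tRNA had no matching feature in the tables analysed here. The 2 planned normalizations for counts were replaced by median-ratio factors computed on the RPM values and by rescaling to the sum of the 5 classes, and the planned count models were not run.

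The fits were tested on simulated data, with 200 changed features, 50 at each fold. In the fit of 760 small RNA features, with the SD of each feature drawn from the fitted prior, 0% of 2-fold, 24% of 4-fold, 76% of 8-fold and 90% of 16-fold changes were recovered, with 2 false calls among 97. With 1 equal SD for all features the recovered shares were 28%, 94%, 100% and 100%, with 14 false calls among 175. In the fit of 477 RefSeq genes with drawn SD, 42% of 2-fold and 98% of 4-fold changes were recovered, with 3 false calls among 173. Of 100 lists of unchanged features in the small RNA simulation with drawn SD, 9 had a fry p below 0.05 and 1 a camera p below 0.05. The simulated noise was independent between features, which real features of 1 table are not.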

Results

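The study profiled small RNA in sperm taken from the cauda epididymis, the storage end of the sperm duct, of C57BL/6 mice. The comparison was between 2 kinds of breeding, labelled original cross and extra cross to wildtype, with 2 mice per cross and 1 library per mouse. The title of the study asks how small RNA differs between sperm that are or are not susceptible to silencing of a LoxP site, the short sequence that Cre recombinase recognises. The labels do not say which cross was susceptible, so the crosses are named here only as original and extra. Each library is given in RPM, read values scaled by the authors to a common library total, for 6 classes of feature, and the 5 small RNA classes (miRNA hairpins, tRNA genes, piRNA loci, rRNA transcripts and repeats) hold 2150 features. The value of 1 read in these 5 classes implies that their RPM scale rests on 632859 reads in original-cross replicate 1, 1782510 in original-cross replicate 2, 1557770 in extra-cross replicate 1 and 4205690 in extra-cross replicate 2. The replicates came as 2 tables, each with 1 library of each cross, and fold changes are therefore also given within each table.

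The clearest difference between the crosses was in the piRNA loci, genomic clusters whose transcripts are cut into the short RNAs that bind PIWI proteins in male germ cells. Reads in the class summed to 16391 and 8826 RPM in the 2 original-cross libraries and to 4068 and 3684 RPM in the 2 extra-cross libraries, which is 4.03-fold and 2.40-fold more in the original cross within the tables of replicates 1 and 2. Of the 121 loci with a mean of at least 10 RPM, 117 were lower in the extra-cross library of both tables and none was higher in both. Their median log2 fold change was -1.82, with -2.19 in replicate 1 and -1.43 in replicate 2. The class was not among the lists set in advance, and its median stayed negative when the libraries were rescaled by median ratios (-1.37) or to the sum of the 5 classes (-1.99). It was -0.27 with each class scaled on its own, which divides out a shift of the whole class. Lists of other cells also differed, with medians of -0.76 for smooth muscle and stroma microRNAs and 1.00 for epididymal epithelium microRNAs. The median of collagen transcripts was -1.02. Among the abundant loci, 18-qE1-36451.1 had 757 and 368.6 RPM in the original cross and 124 and 121 RPM in the extra cross, and 17-qA3.3-27363.1 had 742.7 and 375.8 against 160 and 150 RPM. The loci 5-qF-4633.1 and 5-qF-4633.2 differed less, with 704 and 339 RPM in the original cross and 355 and 285 RPM in the extra cross for 5-qF-4633.2. Loci named for a gene were lower as well, with a median of -1.16 over 12 loci (0.36 with each class scaled on its own) against -1.83 over the 109 loci named for a chromosome band. In that group pi-Gm5878.1 had 75.8 and 48.8 RPM in the original cross and 14.1 and 16.4 RPM in the extra cross, pi-Tmem194.2 had 48.7 and 18.3 against 7.72 and 7.14 RPM, pi-Fth1.1 had 74.3 and 46.6 against 36.6 and 34.2 RPM, and pi-Rplp1.1 had 56.9 and 17.4 against 30.8 and 15.2 RPM.

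**Figure D1:**
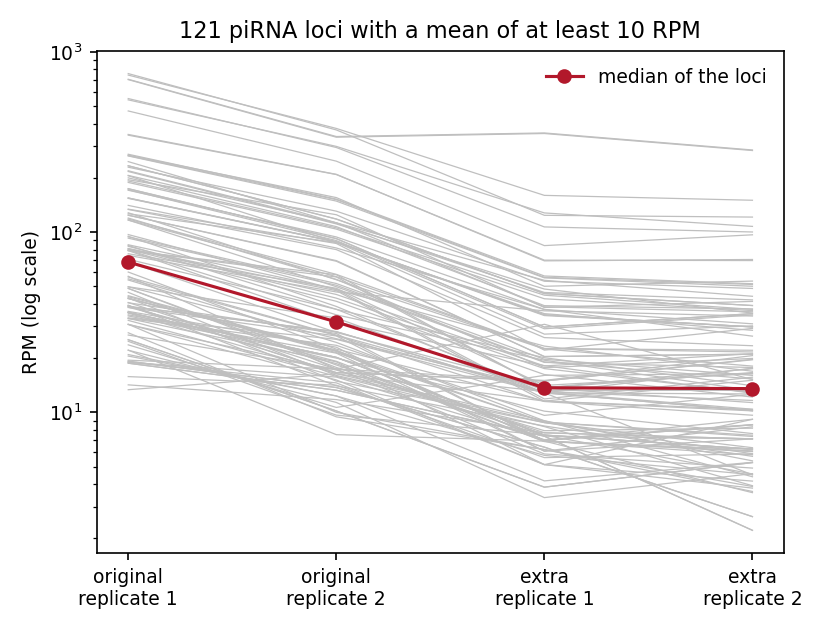
RPM on a log axis of the 121 piRNA loci with a mean of at least 10 RPM in the 4 libraries. Each grey line joins the values of 1 locus, and red points are the median over the loci, which was 68.2 and 31.8 RPM in the original cross and 13.7 and 13.6 RPM in the extra cross.

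No single locus passed the test across all features, which had cross type as its only term. The 5 features with the lowest p among those lower in the extra cross were all piRNA loci, and none passed: 15-qE1-8387.1 (log2 fold change -2.07 ± 0.43, SE), 15-qE1-8387.2 (-2.06 ± 0.43), 15-qE1-3710.2 (-2.20 ± 0.46), 15-qE1-3710.1 (-2.16 ± 0.46) and 15-qD3-14639.1 (-2.15 ± 0.47), each with a limma adjusted p of 0.199. Loci whose names differ only in the last digit hold nearly the same values, so the counts of loci here include near copies and are not counts of independent features. Adjusted over the list alone, 97 of the 121 loci passed, but the list was chosen after its values were seen. With a replicate block 110 loci passed across all features, but the replicate numbers are not known to mark pairs. As a group the loci passed camera with its preset correlation (adjusted p = 2.5e-86), and not with an estimated correlation (adjusted p = 0.758) or in fry (adjusted p = 0.342).

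Several microRNA families were mostly higher in the extra cross in both tables, though no member passed the test. The class as a whole was higher too, at 275809 and 117322 RPM in the original cross and 441544 and 140437 RPM in the extra cross. Of 206 tested hairpins 88 were higher in both tables and 48 lower in both, with a median log2 fold change of 0.20. The counts and medians of all microRNA lists that follow include this shift of the class. All 4 measured members of the miR-29 family were higher in both, with a median log2 fold change of 1.28 (1.44 and 1.12 in replicates 1 and 2, and 0.83 with each class scaled on its own). Hairpin mir-29a had 1509 and 490 RPM in the original cross and 2826 and 960 RPM in the extra cross, and mir-29c had 280 and 115 against 746 and 248 RPM. The copies mir-29b-1 (10.3 and 7.29 against 31.0 and 18.8 RPM) and mir-29b-2 (10.3 and 7.85 against 30.4 and 18.5 RPM) were 2 of the 5 features with the lowest p in this direction. The others were mir-135a-1 (log2 fold change 2.01 ± 0.68, SE), mir-672 (1.35 ± 0.52) and the retroviral repeat RLTR4I_MM_ERV1_Mus (1.44 ± 0.48), with limma adjusted p from 0.261 to 0.336. Hairpin mir-135a-1 had 5.53 and 5.33 against 44.9 and 13.6 RPM, and mir-672 had 6.32 and 10.7 against 28.2 and 17.8 RPM. Both, like the mir-29b copies (10.3 RPM), rest on few reads in original-cross replicate 1, where 1 read is worth 1.58 RPM. The mir-29b copies also hold nearly the same values, so they are not independent members of the miR-29 family. Of the miR-17-92 and miR-106b-25 clusters, 8 of 10 members had a positive log2 fold change (median 0.85, 1.30 under median-ratio scaling and 0.39 with each class scaled on its own) and 7 were higher in both tables, but the most abundant member, mir-92a-1, had 2478 and 844 against 2542 and 673 RPM, and mir-25, mir-93 and mir-92a-2 had log2 fold changes of -0.02, 0.46 and 0.26. The most abundant microRNAs of all, mir-10b and mir-10a, had 85208 and 33062 against 151120 and 45026 RPM and 50397 and 21536 against 111065 and 26893 RPM. Another abundant hairpin, mir-22, had 32835 and 10914 against 40508 and 10432 RPM. In the miR-34 and miR-449 family, of spermatogenic cells, the median over 2 tested members was 0.41 (0.87 under median-ratio scaling and -0.051 with each class scaled on its own). There mir-34c had 1828 and 707 against 1703 and 1132 RPM, mir-34b had 88.5 and 40.4 against 108 and 70.4 RPM, and mir-449a and mir-449c stayed below 5 RPM. The X-linked spermatogenesis cluster had a median of 0.14 over 13 members, with 0.40 and -0.12 in the 2 tables, 0.57 with all 13 positive under median-ratio scaling, 0.0021 scaled to the sum of the 5 classes and -0.32 with each class scaled on its own. Of its members, mir-743b and mir-881 were higher in both (0.76 and 0.74) and mir-871 and mir-465c-1 lower in both (-0.40 and -0.30, but 0.051 and 0.14 under median-ratio scaling).

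MicroRNAs typical of other cells that a sperm preparation can hold went in different directions. Those of epididymal epithelium had a positive log2 fold change in 5 of 5 (median 1.00, and 0.53 with each class scaled on its own) and were higher in both tables in 4, with mir-141 at 1920 and 781 RPM in the original cross and 5466 and 2923 RPM in the extra cross. Of the others, mir-429 was at 904 and 457 against 1862 and 1166 RPM and mir-200a at 819 and 309 against 1440 and 707 RPM, while mir-200b had 687 and 448 against 1458 and 438 RPM. Those of smooth muscle and stroma had a negative log2 fold change in 7 of 7 (median -0.76, -0.31 under median-ratio scaling and -1.22 with each class scaled on its own) and were lower in both tables in 6, with mir-199a-1 at 2270 and 1677 against 444 and 1035 RPM, the near-identical mir-199a-2 at 2268 and 1679 against 444 and 1036 RPM, mir-145a at 1572 and 474 against 1240 and 367 RPM, and mir-143 at 1726 and 1867 against 856 and 2162 RPM. The exception was mir-143, at -1.01 in replicate 1 and 0.21 in replicate 2, and under median-ratio scaling mir-143 and mir-145a turned positive. The smooth muscle and stroma list passed neither camera (adjusted p = 0.112 with the preset and 0.907 with an estimated correlation) nor fry (adjusted p = 0.823). Of 8 blood microRNAs 6 had a positive log2 fold change (median 0.53, 0.99 with all 8 positive under median-ratio scaling and 0.059 with each class scaled on its own), and 4 were higher and 2 lower in both tables: mir-486a and mir-486b each had 841 and 108 against 2790 and 101 RPM, mir-150 had 3633 and 571 against 3483 and 388 RPM, and mir-142b had 419 and 181 against 484 and 218 RPM. In the let-7 family 11 of 12 members had a positive log2 fold change (median 0.26, 0.72 under median-ratio scaling and -0.21 with each class scaled on its own), but the 2 tables differed in direction for 8, with let-7c-2 at 642 and 1137 against 1403 and 1036 RPM, let-7c-1 at 642 and 1139 against 1376 and 1031 RPM, and let-7d and let-7f-2 at 0.06 on the log2 scale. Of 11 members of the imprinted Dlk1-Dio3 cluster 9 were lower (median -0.32, but 0.14 under median-ratio scaling and -0.79 with each class scaled on its own), with mir-434, mir-127, mir-411 and mir-541 at -0.44, -0.67, -0.32 and -0.64, of which mir-434 and mir-411 turned positive there. MicroRNAs reported in sperm of stressed fathers had a positive log2 fold change in 10 of 11 (median 0.54, 1.00 under median-ratio scaling and 0.071 with each class scaled on its own) but were higher in both tables in 5, with mir-204 at 1449 and 737 against 3328 and 714 RPM, mir-30a at 561 and 699 against 652 and 1271 RPM, and mir-375 at 2718 and 488 against 2056 and 412.3 RPM (-0.32, but 0.14 under median-ratio scaling). The Sfmbt2 cluster had 1 member over the minimum, mir-467d, at 15.8 and 5.15 against 29.2 and 8.39 RPM, and mir-467e, mir-466d and mir-467c lay below the minimum.

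Transfer RNA fragments, the most abundant small RNA of mature sperm beside microRNAs, summed to 189637 and 306950 RPM in the original cross and to 173022 and 291164 RPM in the extra cross. The 14 genes for tRNA-Glu-CTC summed to 38466 and 32198 RPM in the original and extra cross of replicate 1 and to 107037 and 100810 RPM in replicate 2. Genes with the same sequence carry the same divided value, so tRNA-Glu-CTC-1-1 to tRNA-Glu-CTC-1-6 each had 3771 and 10810 RPM in the original cross and 3144 and 10275 RPM in the extra cross, and were 6 of the 10 most abundant features. The tRNA-Val-CAC-2 copies had 5478 and 6758 against 5614 and 6473 RPM. The gene tRNA-Val-AAC-1-1 and its copy had 4562 and 6428 against 4245 and 6072 RPM, and tRNA-Glu-TTC-2-1 and its copy had 1358 and 3133 against 1374 and 3401 RPM. For tRNA-Lys-CTT the 2-1 and 3-1 genes with their copies had log2 fold changes of 0.06 and -0.10. For tRNA-Gly-GCC the 4-1 gene was at -0.51 and the 2-1 gene with its copies at -0.07. The tRNA-His-GTG-2-1 gene had 1666 and 1103 against 1114 and 879 RPM, and the tRNA-Asp-GTC-1-1 gene had 202 and 890 against 82.6 and 635 RPM. Of 15 tRNA-Asp-GTC genes 14 were lower in both tables, but 13 of these are copies with 1 shared value, which sets the median of -0.88 (-0.42 under median-ratio scaling). That value was 0.58 without extra-cross replicate 1 and 0.18 without original-cross replicate 2. With 1 library left out, the difference between the tables enters the value, so these do not contradict the direction within the tables. The medians of tRNA-Glu-CTC (-0.17), tRNA-His-GTG (-0.45), tRNA-Lys-CTT (-0.10), tRNA-Gly-GCC (-0.071) and tRNA-Val-CAC (-0.013) turned positive under median-ratio scaling (0.30, 0.0087, 0.36, 0.39 and 0.45).

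The summed reads on repeats went in opposite directions in the 2 tables. They were 11451 RPM in the original cross and 7741 RPM in the extra cross of replicate 1, and 4668 and 5489 RPM in replicate 2. Most single repeats did not follow the sum: of 64 tested, 49 were lower in both tables and 5 higher in both. Their median log2 fold change was -0.47, with -0.61 and -0.37 in replicates 1 and 2. The medians of LINE L1, B1 and B2 elements lay near that of the class. All 26 tested LINE L1 elements had a negative log2 fold change (median -0.50), and 24 were lower in both tables. The young L1MdTf_I_L1_Mus had 53.0 and 43.6 RPM in the original cross and 25.7 and 27.2 RPM in the extra cross, L1MdTf_II_L1_Mus had 50.7 and 42.6 against 23.9 and 26.4 RPM, L1MdGf_I_L1_Mus had 27.6 and 33.5 against 17.4 and 27.5 RPM, and HAL1-1H_Cpo_L1_Cavia had 84.9 and 46.3 against 28.2 and 76.3 RPM. Of the intracisternal A particles, IAPEZI_ERV2_Mus had 95.1 and 58.4 against 52.0 and 47.5 RPM and IAPLTR1a_I_MM_ERV2_Mus had 80.2 and 59.6 against 52.1 and 54.8 RPM. MERVL_ERV3_Mus had 37.4 and 30.01 against 27.5 and 21.6 RPM, and the ETn elements stayed below 2 RPM in all 4 libraries. The short B1 and B2 elements had medians of -0.46 over 8 and -0.51 over 6 features, with PB1_SINE1-7SL_Rodentia higher (0.18), B1_Mm_SINE1-7SL_Mus and B1_Mus1__ lower (-0.54 and -0.46), and B2_Mm1a_SINE2-tRNA_Mus and B2_Mm1t_SINE2-tRNA_Mus lower (-0.68 and -0.44). Under median-ratio scaling the L1 median was -0.058 with 19 of 26 negative, the B1 and B2 medians were -0.029 and -0.079, and IAPLTR1a_I_MM_ERV2_Mus and MERVL_ERV3_Mus turned positive (0.090 and 0.0042). Ribosomal RNA was dominated by a transcript of CT010467.1 on chromosome 17 (39846353 to 39848201, minus strand, GRCm38), at 58717 and 57008 against 39099 and 54408 RPM. The neighbouring CT010467.1 transcript had 688 and 746 against 522 and 929 RPM. The mitochondrial mt-Rnr2 and mt-Rnr1 had 447 and 453 against 865 and 714 RPM and 207 and 190 against 304 and 222 RPM.

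**Figure D2:**
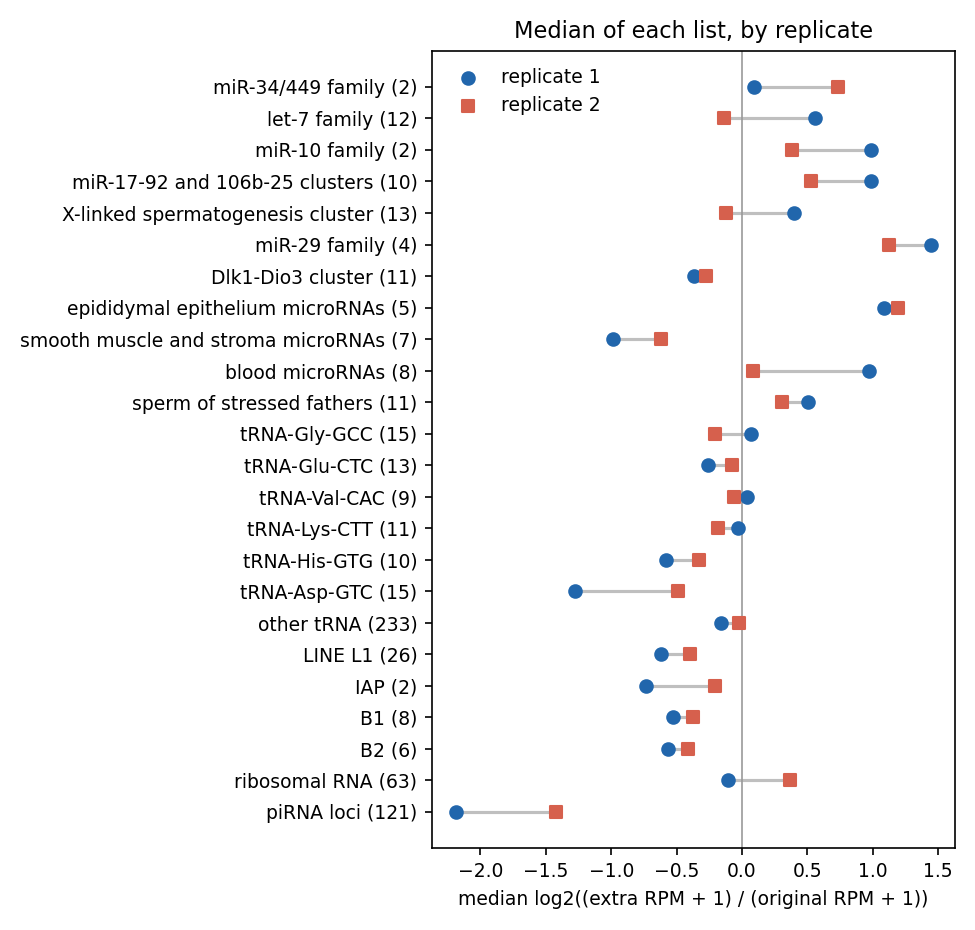
Median log2 fold change, extra over original cross, of the small RNA lists with at least 2 tested members in replicate 1 (circles) and replicate 2 (squares), with the number of tested members in brackets. Of the lists plotted, which leave out the subsets of piRNA loci by kind of name, the piRNA loci lie lowest in both replicates (-2.19 and -1.43) and the miR-29 family highest in replicate 1 (1.44).

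Across the 760 small RNA features with a mean of at least 10 RPM, 0 passed limma at a Benjamini-Hochberg adjusted p of 0.05, and 112 had an unadjusted p below 0.05. Of these 104 were piRNA loci, all lower in the extra cross, 2 were other features lower and 6 were higher. With voom weights 0 passed as well, and 102 had an unadjusted p below 0.05. With a replicate block 171 features passed limma, of which 110 were piRNA loci, all lower. That fit took each variance from the trend across features, and the replicate numbers are not known to mark pairs. When each class was scaled and fitted on its own 10 piRNA loci passed, 8 higher and 2 lower relative to their class. Of the 20 lists set in advance that had at least 3 tested members, 8 passed camera with the preset correlation, at adjusted p from 0.00026 to 0.026. LINE L1 ranked lower than the other features, though its median (-0.50) lay near that of all 64 tested repeats (-0.47). The miR-17-92 and miR-106b-25 clusters, the miR-29 family, and the epididymal epithelium, stressed-father and let-7 microRNAs ranked higher. So did ribosomal RNA and the tRNA genes outside the named isoacceptors. The last of these had a negative median (-0.093, and 0.36 under median-ratio scaling) and a fry direction opposite to that of camera. The ribosomal RNA median was 0.13 but -0.0037 when scaled to the sum of the 5 classes, and 58 of its 63 members differed in direction between the tables. In each library 32 ribosomal RNA features held 1 shared value, among them Rn5s and n-R5s108. The ribosomal RNA median, the count of 58 and the camera result therefore include copies and do not rest on independent features. With an estimated correlation none of the 20 passed, at an adjusted p of 0.907 for each of these 8, and none passed fry, whose lowest adjusted p was 0.823. Adjusted over the list alone, 0 members of these lists passed. Median-ratio scaling moved the median of all features by 0.45 on the log2 scale, and scaling to the sum of the 5 classes moved it by -0.13. The median-ratio factors include the piRNA loci and features below 10 RPM. With factors from the other 4 classes at a mean of at least 10 RPM, the piRNA median was -1.74, against -1.37 with the factors used here. Which sign changes under median-ratio scaling would remain with those other factors was not tested.

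The shares of microRNA and tRNA differed more between the tables than between the crosses. MicroRNAs took 49.6% and 66.0% of the reads of the 5 classes in the original and extra cross of replicate 1 and 23.6% and 28.1% in replicate 2. The tRNA class took 34.1% and 25.8% in replicate 1 and 61.7% and 58.3% in replicate 2. The piRNA share was 2.36% ± 0.83 (SD, 2 mice) in the original cross and 0.673% ± 0.092 (SD, 2 mice) in the extra cross. The rRNA share was 11.7% ± 0.59 against 9.07% ± 3.7, and the repeat share 1.499% ± 0.79 against 1.13% ± 0.040, with 2.06% against 1.16% in replicate 1 and 0.938% against 1.0996% in replicate 2. An exact permutation test of 2 against 2 mice cannot go below p = 0.333, two-sided, which the piRNA share reached, so this test can call no share different. Across the 760 features the fold changes of the 2 tables had a Pearson r of 0.75 and a Spearman rho of 0.64, and 66.2% had the same sign. With the libraries of the 2 tables crossed, r was -0.42, rho was -0.23 and 33.4% had the same sign. A difference between the tables enters the crossed fold changes with opposite signs, which lowers r. The replicate numbers are not known to mark pairs. By replicate number and without the piRNA loci r was 0.46 over 639 features. These are correlations across features, which are not independent replicates.

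Reads on RefSeq transcripts were compared separately, because in original-cross replicate 1 the RefSeq values stand on another scale: 1 read was worth 0.0603 RPM there and 1.58 RPM in the other classes, a ratio of 26.2, while the ratio was 1 in each of the other 3 libraries. The RefSeq values of that library were multiplied by this ratio, a step chosen after seeing the data, and transcripts were summed to genes. Collagen fragments were lower in the extra cross: all 20 tested collagens had a negative log2 fold change (median -1.02, and -0.47 under median-ratio scaling) and 19 were lower in both tables. The median of all 477 tested RefSeq genes was -0.50. The type I collagen gene Col1a1 had 1244 and 1700 RPM in the original cross and 439 and 643 RPM in the extra cross (log2 fold change -1.45 ± 0.34, SE). Col1a2 had 682 and 801 against 311 and 350 RPM, Col3a1 had 531 and 626 against 233 and 244 RPM, and Col6a2 had 243 and 246 against 110 and 100.1 RPM. The basement membrane gene Lama2 had 26.9 and 25.8 against 7.06 and 11.2 RPM and Serpinf1 had 33.2 and 34.2 against 13.5 and 14.1 RPM. Wtap and Gm20742 were also among the 5 lowest p, at 50.8 and 22.2 against 6.21 and 10.2 RPM and at 75.4 and 35.4 against 16.5 and 12.2 RPM. Small nucleolar RNAs, guides for the modification of ribosomal RNA, had a positive log2 fold change in 24 of 31 and were higher in both tables in 17. Their median was 0.50, with 0.18 and 0.73 in the 2 tables, 0.96 without original-cross replicate 1 and 1.03 under median-ratio scaling. Examples were Snord2 at 374 and 249 against 1094 and 413 RPM, Snord104 at 179 and 155 against 230 and 171 RPM, Snord118 at 0.20 and Snord14d at -0.46 on the log2 scale. Snord43, Snord66, Snord4a, the secreted-protein gene Cuzd1 and the epididymal lipocalin Lcn5 had the lowest p among higher genes, with log2 fold changes of 1.11, 1.12, 0.95, 0.78 and 1.62.

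Transcripts of epididymal epithelium had a positive log2 fold change in 7 of 7 tested genes (median 0.61), and 4 were higher in both tables. The median was 1.16 under median-ratio scaling and 0.077 without original-cross replicate 1. Lcn5 had 4.74 and 23.0 RPM in the original cross and 21.8 and 55.9 RPM in the extra cross, Adam7 had 23.7 and 39.3 against 49.4 and 45.1 RPM, Clu had 41.1 and 36.5 against 44.3 and 53.5 RPM, and Gpx5 had 74.3 and 118 against 140.9 and 89.0 RPM. Of the blood transcripts Lyz2 was measured at 94.0 and 41.1 against 60.0 and 30.7 RPM, and Ptprc, Hbb-bs and Hbb-b1 stayed below 5 RPM. Sperm transcripts were close to the floor, with Odf2, Gapdhs, Odf1 and Prm1 each at no more than 3.16 RPM in any library. Genes of the piRNA pathway (Pld6, Piwil2, Tdrd1 and Mybl1) stayed below 2 RPM, and of the DNA methylation genes Trim28 and Tet2 reached 6.42 and 6.17 RPM, with Dnmt1 and Tet1 lower. No gene of these 3 lists reached the minimum of 10 RPM for the test. The small nuclear RNAs had a median of -0.0026 over 14 genes, 0.56 under median-ratio scaling, with Rnu1a1, Rnu5g, Rnu2-10 and Rnu1b1 at -0.71, -0.11, -0.49 and -0.0026. Among the Y RNAs Rny3 had 997 and 1171 against 440 and 961 RPM and Rny1 had 839 and 691 against 798 and 858 RPM. Vaultrc5 was at 0.37, Rn7sk at -0.57, and Rn7s1 and Rn7s2 each at -0.18 on the log2 scale. The most abundant RefSeq entries were Rn28s1 (60535 and 43068 against 37167 and 39272 RPM), Lars2, Gm15564, Gm46178 and Gm41051, the last 4 at -0.45, -0.13, -0.39 and -0.14.

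Of 477 RefSeq genes with a mean of at least 10 RPM, 0 passed limma, with 114 at an unadjusted p below 0.05 and a lowest adjusted p of 0.165. With a minimum of 50 RPM 6 of 69 passed, all of them collagens and all lower. Without original-cross replicate 1, the rescaled library, 7 genes passed, of which 6 were small nucleolar RNAs higher in the extra cross (Snora16a, Snord99, Snord49a, Snord89, Snora68 and Snord2) and only Col1a1 was lower. Without original-cross replicate 2 the rescaled library stood alone for the original cross. The collagen median was then -1.04 and Lcn5 was higher (2.65). Other small nucleolar RNAs, Snord61 (-1.86) and Snora21 (-1.95), were lower there. Every fit with 1 library left out also takes in the difference between the tables. Without extra-cross replicate 1 Lcn5 passed as higher (its log2 fold change was 0.59, not passing, without original-cross replicate 1, where it has 3 reads) and Gm20742 as lower, and without extra-cross replicate 2 Wtap passed as lower. Values as deposited, not rescaled, gave 0 calls and a collagen median of 1.16, which has the opposite sign. Median-ratio scaling, which moved the median of all genes by 0.54, left the collagen median at -0.47. Adjusted over the list alone 13 of 20 collagens passed, a list chosen after its values were seen. By camera with the preset correlation the collagens were lower (adjusted p = 1.3e-05) and the epididymal transcripts, small nucleolar and small nuclear RNAs higher (adjusted p = 9.3e-08, 1.6e-17 and 0.0048). With an estimated correlation none passed, at adjusted p of 0.176 for the first 3 and 0.442 for the small nuclear RNAs, whose median and fry direction were negative although camera put them higher than other genes. The fry directional test gave an adjusted p of 0.072 for the collagens and 0.824 for the epididymal transcripts.

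**Figure D3:**
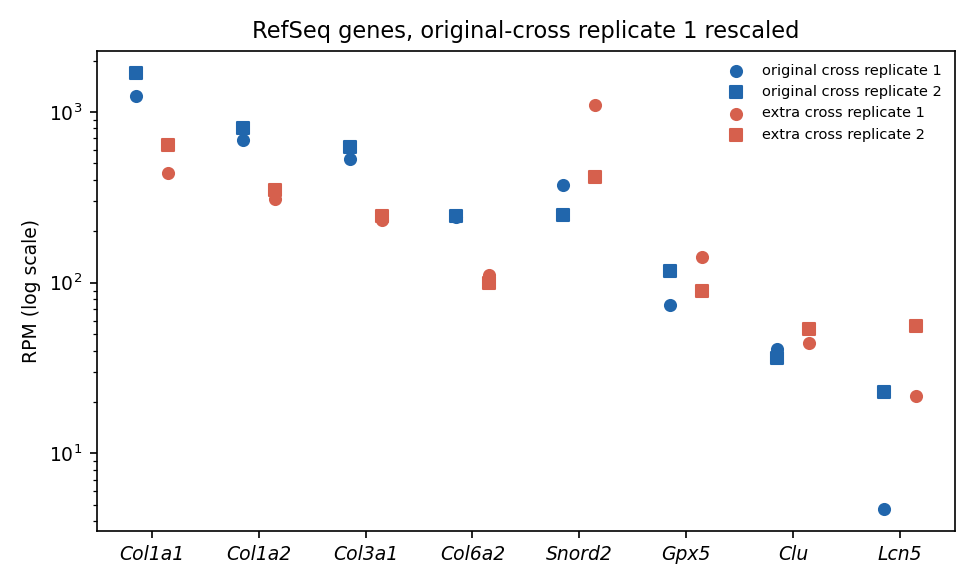
RPM on a log axis of 8 RefSeq genes in the 4 libraries, with original-cross replicate 1 multiplied by 26.2. With that factor the 4 collagens lie lower in both extra-cross libraries than in both original-cross libraries, Snord2 lies higher, and Gpx5 overlaps between the crosses.

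The tables also list 1 feature of the engineered locus, LSD1_floxed, a reference sequence of the floxed Lsd1 gene (Kdm1a). It had 5.37 RPM after rescaling and 3.32 RPM in the original cross, and 4.08 and 2.18 RPM in the extra cross, which stand for 3.4, 5.93, 6.36 and 9.17 weighted reads. The values of the crosses overlapped. The exact permutation test gave p = 0.667, two-sided, where 0.333 is the smallest p that 2 against 2 mice can give. The feature may also take reads of the normal Lsd1 sequence, and Kdm1a itself stayed below 1 RPM in all 4 libraries.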

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

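The sign of the log2 fold change was kept under every setting run by 40 named small RNA features and 9 named RefSeq genes, and turned under at least 1 setting for the other 66 and 27. The tests across features were limma fits, and the voom weights, the fit with no variance trend, the fit with identical rows counted once, and all settings for the piRNA loci, the collagens and RefSeq were chosen after seeing the data. The count of 0 small RNA features held under both pseudocounts, both filters, each left-out library (a lone library is then assumed to vary like the others), both scalings across all classes, no variance trend, voom weights and identical rows counted once, with 36 to 210 features at an unadjusted p below 0.05 in the settings other than the block. It was 10 with each class scaled and fitted on its own. The 2 replicate numbers are not said to mark a shared day or litter, so the pairing is not part of the design: with the replicate block 171 features passed, 135 lower and 36 higher, and 110 of the lower ones were piRNA loci, and the deviations of same-numbered libraries from their group means had r = 0.87 across the 760 features. That fit has 1 residual degree of freedom. Its prior degrees of freedom were infinite, against 3.07 in the main fit, so each feature took its variance from the trend alone. The RefSeq count was 0 with the block. Crossing the pairs turned the agreement of the fold changes to r = -0.42. A difference between the tables enters the crossed fold changes with opposite signs, so that value cannot test the agreement within tables. By replicate number, a minimum of 1 RPM gave r = 0.60. The number of lists passing camera with the preset correlation, 8, was 10 with the block, 4 with no filter, 2 with a minimum of 50 RPM and 0 with an estimated correlation, and ranged from 4 to 9 over the left-out libraries, the 4 being without extra-cross replicate 1. Without the 10 most abundant features the difference in share was -2.83 percentage points for piRNA and 0.19 for rRNA. The piRNA median of -1.82 was negative under all 15 other settings. It was -1.25 with a pseudocount of 10, -0.79 with no filter, where most loci are near the floor, and -0.27 with each class scaled on its own, which divides out a shift of the whole class. The collagen median was -0.80 with a pseudocount of 10, -0.62 with no filter, -1.19 with a minimum of 50 RPM, -0.47 with median-ratio scaling and 1.16 as deposited. The RefSeq count was 6 with a minimum of 50 RPM, which tests 69 genes, and 1 to 41 over the left-out libraries. The planned count models were not run, since the values are not counts. The precision of low small RNA features is limited most in original-cross replicate 1, where 1 read is worth 1.58 RPM. Except where a construction is named, the cause was not tested.

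None of the sign changes that follow was in a feature that passed the test as reported. Under median-ratio scaling the log2 fold change became positive for the first CT010467.1 transcript (0.14), tRNA-Glu-CTC-1-1 (0.30), mir-92a-1 (0.32), mir-25 (0.45), mir-871 (0.051), mir-465c-1 (0.14), mir-434 (0.018), mir-411 (0.14), mir-143 (0.063), mir-145a (0.11), mir-150 (0.15), mir-375 (0.14), tRNA-Gly-GCC-2-1 (0.39), tRNA-Val-CAC-2-1 (0.45), tRNA-Lys-CTT-3-1 (0.36), tRNA-His-GTG-2-1 (0.0087), tRNA-Val-AAC-1-1 (0.37), HAL1-1H_Cpo_L1_Cavia (0.033), IAPLTR1a_I_MM_ERV2_Mus (0.090), MERVL_ERV3_Mus (0.0042), B2_Mm1t_SINE2-tRNA_Mus (0.0040), the second CT010467.1 transcript (0.42), Lyz2 (0.030), Snord14d (0.10), Rnu5g (0.45), Rnu2-10 (0.068), Rnu1b1 (0.56), Rn7s1 (0.37), Rn28s1 (0.15), Lars2 (0.12), Gm15564 (0.44), Gm46178 (0.17) and Gm41051 (0.42), with the identical tRNA copies alike. With scaling to the sum of the 5 classes it became negative for mir-22 (-0.017), let-7d (-0.078), let-7f-2 (-0.072), tRNA-Lys-CTT-2-1 (-0.074) and tRNA-Glu-TTC-2-1 (-0.068). With each class scaled on its own the sign turned for mir-22 (-0.35), mir-34c (-0.18), let-7d (-0.41), let-7f-2 (-0.40), mir-93 (-0.010), mir-92a-2 (-0.21), mir-142b (-0.23), tRNA-Gly-GCC-2-1 (0.034), tRNA-Val-CAC-2-1 (0.091), tRNA-Val-AAC-1-1 (0.011), the second CT010467.1 transcript (0.25), 5-qF-4633.2 (1.01), 5-qF-4633.1 (1.01), pi-Fth1.1 (0.89) and pi-Rplp1.1 (1.06), of which the last 4 passed there. With RefSeq as deposited it became positive for Lyz2 (1.66), Snord14d (1.71), Rnu1a1 (1.59), Rnu5g (2.15), Rnu2-10 (1.72), Rnu1b1 (2.20), Rny3 (1.61), Rn7sk (1.75), Rn7s1 (1.77), Col1a1 (0.89), Col1a2 (1.17), Col3a1 (1.05), Col6a2 (1.07), Rn28s1 (1.94), Lars2 (1.91), Gm15564 (2.22), Gm46178 (1.96), Gm41051 (2.20), Wtap (0.12), Gm20742 (0.36), Lama2 (0.43) and Serpinf1 (0.73). Leaving out 1 library at a time turned the sign, with these ranges, for mir-10b (-0.24 to 1.51), mir-10a (-0.29 to 1.75), mir-22 (-0.86 to 1.097), tRNA-Glu-CTC-1-1 (-1.02 to 0.69), mir-34c (-0.40 to 0.97), mir-34b (-0.018 to 1.09), let-7d (-0.80 to 0.92), let-7f-2 (-0.45 to 0.58), mir-92a-1 (-1.10 to 0.81), mir-25 (-0.87 to 0.84), mir-93 (-0.33 to 1.24), mir-92a-2 (-0.76 to 1.27), mir-743b (-0.32 to 1.84), mir-871 (-0.81 to 0.017), mir-465c-1 (-1.11 to 0.51), mir-434 (-1.07 to 0.18), mir-411 (-0.65 to 0.0064), mir-200b (-0.34 to 1.39), mir-143 (-1.07 to 0.27), mir-145a (-1.23 to 0.52), mir-150 (-1.89 to 1.27), mir-486a (-1.57 to 3.21), mir-142b (-0.36 to 0.84), mir-204 (-0.53 to 1.69), mir-375 (-1.56 to 0.92), tRNA-Gly-GCC-2-1 (-0.23 to 0.091), tRNA-Val-CAC-2-1 (-0.16 to 0.14), tRNA-Lys-CTT-2-1 (-0.23 to 0.35), tRNA-Lys-CTT-3-1 (-0.24 to 0.032), tRNA-Asp-GTC-1-1 (-2.35 to 0.58), tRNA-Val-AAC-1-1 (-0.35 to 0.17), tRNA-Glu-TTC-2-1 (-0.59 to 0.72), HAL1-1H_Cpo_L1_Cavia (-1.13 to 0.28), PB1_SINE1-7SL_Rodentia (-0.057 to 0.42), the second CT010467.1 transcript (-0.46 to 0.38), pi-Rplp1.1 (-1.35 to 0.30), Gpx5 (-0.071 to 0.59), Lyz2 (-1.11 to 0.061), Snord14d (-1.03 to 0.11), Snord118 (-0.22 to 0.61), Rnu5g (-0.25 to 0.032), Rnu1b1 (-0.61 to 0.61), Rny1 (-0.020 to 0.26), Vaultrc5 (-0.14 to 0.87), Rn7s1 (-0.90 to 0.53), Gm15564 (-0.33 to 0.076) and Gm46178 (-1.02 to 0.23). Leaving out 1 library leaves 1 cross with a library in only 1 table, so the difference between the tables enters these ranges. A sign can turn there although both tables agree. Within the tables of replicates 1 and 2, mir-10b was higher in both (0.83 and 0.45) and tRNA-Asp-GTC-1-1 lower in both (-1.28 and -0.49). Others, such as mir-486a (1.73 and -0.098), differed in sign between the tables. Beyond this construction the cause was not tested.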

Other observations

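The tests of explanations in this part were chosen after the values were seen, as was the list of collagens, while the microRNA lists and their camera tests were set in advance. Each SD in this part was taken over loci, genes or microRNAs, and does not measure the spread between mice. The replicate tables differed strongly in particular transfer RNAs, whatever the cross. The genes for tRNA-Asn-GTT summed to 86.9 and 79.6 RPM in the original and extra cross of replicate 1 and to 1345 and 1749 RPM in replicate 2, which is 15.5-fold and 22.0-fold more. The same was seen for tRNA-Phe-GAA, at 34.8 and 30.1 RPM against 583 and 1042 RPM, for tRNA-Ile-AAT, at 181 and 161 against 1323 and 2086 RPM, and for the initiator tRNA-iMet-CAT, at 5652 and 6545 against 16680 and 17603 RPM. By contrast tRNA-Val-CAC had 33657 and 34603 RPM in replicate 1 and 36503 and 35190 RPM in replicate 2. The first principal component of the 760 features took 65.2% of the variance and separated the 2 tables, and the second took 31.5% and separated the crosses.

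The piRNA loci lower in the extra cross are the pattern most open to follow-up. A difference in library scaling is argued against, since scaling on the other 4 classes left their median log2 fold change at -1.74, with an SD of 0.43 over the loci and 120 of 121 negative. The shallowest library, original-cross replicate 1, is not the whole source, because the replicate 2 table alone had a median of -1.43 (SD 0.48). Carry-over of testicular germ cells, more in the original cross, cannot be told apart from a difference in the sperm: the X-linked spermatogenesis cluster microRNAs had a median of 0.14 (SD 0.45), but their level in sperm could hide a small share of such cells. In the same comparison collagens and stromal microRNAs had negative medians (-1.02 and -0.76) and epididymal epithelium microRNAs a positive one (1.00). Whether a difference in other cells of the preparations bears on the piRNA loci was not tested. The cross type itself stays open and untested, with 2 mice per cross.

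The tested collagens had negative log2 fold changes, as did the stromal microRNAs, while those of the epithelial microRNAs were positive, but no gene passed and with an estimated correlation no list did (adjusted p = 0.176, 0.907 and 0.907). The rescaled library does not account for the collagens, whose median in the replicate 2 table alone was -0.91 (SD 0.42). The epididymal epithelium microRNAs lay 0.81 above the median of all tested microRNAs (SD 0.43), led by mir-141. This argues against a smaller carry-over of all other cells alike only if they mark carried-over cells, which was not tested. The summed epididymal transcripts had 170 and 320 RPM in the original cross and 373 and 331 RPM in the extra cross. The summed blood transcripts were lower, at 111 and 51.8 against 71.6 and 45.2 RPM, while the blood microRNAs had a positive median (0.53). A candidate explanation is less carried-over connective tissue in the extra-cross preparations. The smooth muscle and stroma microRNAs, a list set in advance, had a median that differed from that of all tested microRNAs by -0.96. The SD over the list members was 0.48, and mir-199a-1 and its near copy mir-199a-2 were both at -1.52. The abundant mir-143 was at -0.40 and at 0.21 in replicate 2, against this explanation. How many of these genes sperm or epididymal epithelium also express was not tested, and a difference that goes with the cross stays open.

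The low RefSeq values of original-cross replicate 1 may come from division by another read total. The 1-read value differed 26.2-fold between RefSeq and the other classes in that library and by a ratio of 1 in the others. Less RefSeq RNA in that library is argued against, since the median log2 ratio of 477 genes to the mean of the other 3 libraries was -4.18 as deposited and 0.52 (SD 0.69) after multiplying by that ratio. Which of the read totals, 632859 or 16582100, belongs to the library was not tested.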
